A study of Solanum lycopersicum with 4 samples.

How the data were processed

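RNA sequencing was done on total RNA of dissected tomato shoot apical meristems. Per the labels' protocols, seedlings grew in a greenhouse for 2 to 12 days, were fixed in acetone and dissected, RNA was extracted with an RNeasy kit and libraries were made with an Illumina TruSeq RNA kit. The 4 libraries fall into 2 groups by the stage given in the labels, vegetative after 6 leaves and transitional. The titles letter the vegetative replicates C and D, whereas the descriptions and column names letter them A and B; the letters of the titles are used here. No replicate letter is shared between the groups in the titles, so no pairing was used. The study's design text also names a comparison with a mutant, late termination, which is not analysed here.

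The authors deposited a normalised signal per gene and library: gene counts divided by 1 size factor per library. The submitters' processing notes name TopHat2 2.0.10, HTSeq 0.6.1p1 and DESeq2 1.6.3, without a role or order. The genome build and annotation are not given in the sources used here. In each library 100% of the deposited signal values were whole multiples of 1 step, within a relative tolerance of 1e-06, so the whole reads and the authors' size factors (0.725, 1.02, 0.987 and 0.988 for vegetative C and D and transitional A and B) could be recovered. DESeq2 size factors computed from these 4 libraries were 1.08 to 1.09 times the authors'. How the authors' counting treated strand, overlapping genes and near-identical copies is not given in the sources used here. Genes of such families, among them photosynthesis and wound genes, are uncertain where reads could be split.

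The design written before the data were examined named edgeR's quasi-likelihood test for counts and limma for a file with normalised values alone. The values being normalised, limma 3.58.1 (trend) in R 4.3.3 was used on log2(value + 1) for genes with a mean of at least 5 normalised counts, with group as the only term and a Benjamini-Hochberg adjusted p under 0.05. A fold change on this scale understates the change of low genes. The residual degrees of freedom were 2 and the prior degrees of freedom 5.18. edgeR 4.0.16 on the recovered reads, an alternative added after the data were seen, called 531 genes higher and 243 lower, and 744 of the 762 genes called by limma were shared. Its biological coefficient of variation was 9.53%.

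Of the 34722 identifiers, 0 matched the RefSeq gene table of tomato (assembly SLM_r2.1), and the files do not pair identifiers with names or descriptions. Single genes are therefore limited to 2 identifiers that rose and 2 that fell, the largest changes on the log2(value + 1) scale under a rule set before the data were examined: called, a mean of at least 10 normalised counts, and both transitional values on the same side of both vegetative values. That rule also asked for chosen list members by name, which are not printed.

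Of 24 gene lists written before the data were examined, 9 rested on gene descriptions and were not run. The other 15 were lists of identifiers recalled from published tomato nomenclature, matched on their first 14 characters, and 158 of 159 entries were found. Neither the file nor the reference could be used to check an identifier's place in its list. The lists cover MADS-box, B and C class, floral transition, CETS, SBP-box, AP2-like, meristem maintenance, boundary, gibberellin, clock, PIN, photosynthesis, epidermis, heat shock and wound genes. Lists with at least 3 tested members were tested two-sided with limma's camera (preset correlation 0.01), adjusted over the 15 lists. They were tested again with an estimated correlation and with fry. Camera with an estimated correlation also refers its statistic to the residual degrees of freedom, 2 here, and the preset form to far more. The p-values of the estimated form are therefore larger for that reason too.

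Alternatives were DESeq2 1.42.0 and limma-voom on the recovered reads, DESeq2 size factors, library size scaling, no filter, a filter of 1 CPM in 2 libraries, pseudocounts of 0.5 and 5, a test against a 1.5-fold change, and leaving out each library. Those planned for a count test were applied within limma. TMM scaling, edgeR and list counts without each library were added after the data were seen. Permutation and exact tests used SciPy 1.17.1 in Python 3.11.15. On simulated data with 200 changed genes in each of 5 simulations of transitional against vegetative libraries (18720 genes tested on average), limma recovered 84.0% of 2-fold and 99.2% of 4-fold changes, with 4.18% false among the genes called. All simulated libraries shared 1 trend of spread by expression level, and the lowest genes were never changed. The real replicate pairs differed in spread (chi-square per degree of freedom 3.41 for C against D and 15.4 for A against B). These rates therefore need not hold for the real data.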

Results

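Gene expression was measured by RNA sequencing in shoot apical meristems of wild-type tomato (Solanum lycopersicum), the small dome of dividing cells at the tip of the shoot that makes leaves and later turns to making flowers. Meristems were dissected from acetone-fixed greenhouse seedlings at a pair of stages. The vegetative group held 2 libraries (replicates C and D) from meristems that had already produced 6 leaves, and the transitional group held 2 libraries (replicates A and B) from meristems passing to flowering. Vegetative replicates C and D held 16141074 and 23043526 reads in genes, and transitional replicates A and B held 21977345 and 22094423. The 10 most abundant genes took between 3.53% and 3.92% of the reads of a library. A gene at 0 in a library could still have stood at up to 0.13 to 0.19 CPM (3 reads of that library's total), a limit that covers counting error only. Of the 34722 genes in the table, 10701 had no read in any of the 4 libraries.

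The vegetative replicates lay closer together than the transitional ones. Over the 14600 genes with a mean of at least 100 normalised counts, the standard deviation of the log2 difference was 0.187 between vegetative C and D and 0.274 between transitional A and B. In the same genes, 33 stood more than 2-fold apart between C and D and 113 between A and B, against 283 to 372 between libraries of different stages. The chi-square statistic per degree of freedom was 3.41 for C against D and 15.4 for A against B, so both pairs differed by more than read counting gives and each library was counted as 1 replicate. The labels do not say whether replicates came from separate sets of plants, and the p-values therefore measure only the spread between these samples, which may be technical.

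The comparison of the stages addressed which genes differ between the wild-type meristem at floral transition and the vegetative one. Expression rose for 529 genes and fell for 233 at the transition, out of 19607 tested. The rises were also larger: 327 genes rose and 73 fell by more than 2-fold, and 49 rose and 6 fell by more than 16-fold. The genes that rose started low, with a median of 135 normalised counts in vegetative and 362 in transitional meristems, whereas those that fell went from a median of 801 to 487. Among the risen genes, 17 had no read in either vegetative library. The median log2 change was 1.26 for genes that rose and -0.74 for genes that fell (limma on log2 values, Benjamini-Hochberg adjusted p under 0.05, n = 2 per group). All 762 called genes had both transitional values on the same side of both vegetative values, as did 49.3% of the tested genes, where chance gives 33.3%. Without vegetative replicate C or without D, limma called 0 genes in either direction, with 1577 and 1867 genes at an unadjusted p under 0.05. Without transitional replicate A the counts were 646 higher and 478 lower, and without B 776 and 433.

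**Figure D1:**
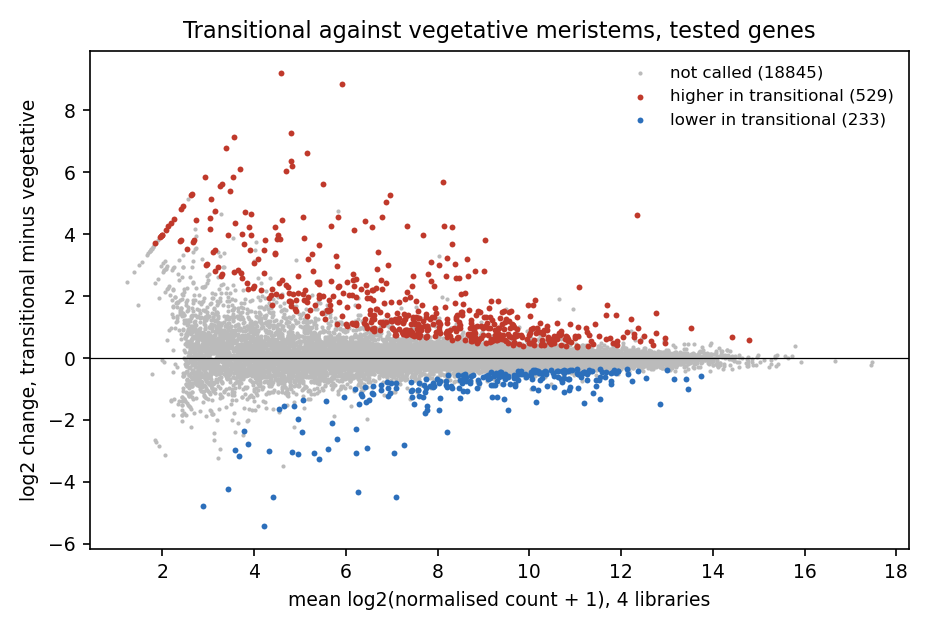
Each point is 1 of the 19607 tested genes, with its mean log2(normalised count + 1) over the 4 libraries on the horizontal axis and its log2 change, transitional minus vegetative, on the vertical axis. Red points are the 529 genes called higher in transitional meristems and blue points the 233 called lower; the largest changes lie above 0.

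Several of the largest rises on the log2(value + 1) scale started from near silence in the vegetative libraries. Solyc08g006860.2 had no read in either vegetative library and stood at 838 and 408 normalised counts in transitional A and B, which was at least 363-fold higher against a floor of 3 reads over the vegetative group (log2 change 9.19, SE 0.42, limma adjusted p = 0.000369). Solyc01g067540.1 stood at 6.90 and 0 in vegetative C and D and at 1759 and 939 in transitional A and B (log2 change 8.84, SE 0.85, limma adjusted p = 0.00383). Solyc10g074440.1 fell from 160 and 92.9 in vegetative C and D to 1.01 and 3.04 in transitional A and B, the transitional values together resting on 4 reads (log2 change -5.43, SE 0.49, limma adjusted p = 0.00319). Solyc01g014290.1 went from 34.5 and 41.1 to 1.01 and 0, the transitional values resting on 1 read (log2 change -4.77, SE 0.60, limma adjusted p = 0.00824). Its vegetative to transitional ratio was 75.7, with an exact 95% counting interval of 13.1 to 3040. None of these 4 genes belonged to a gene list described here. The files do not pair the identifiers with gene names, so no further single genes are given.

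Gene groups are described by lists whose identifiers were recalled from published tomato nomenclature and could not be checked against a name table. A list's result therefore describes the identifiers placed in it. Members that rose or fell are those called by limma, unless another tool is named. Without vegetative replicate C, or without D, limma called 0 members of every list, as it called 0 genes in all.

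MADS-box genes of the inflorescence and flower meristem, transcription factors that specify floral meristem fate, stood higher at the transition. Of 11 tested members 8 rose and none fell, with log2 changes of 1.10 to 6.19 among those that rose, and 10 rose when adjusted over the list alone. Over all members the median was 3.65 on the log2 scale, and without transitional replicate A, or without B, 7 rose. Regulators of floral transition and inflorescence form also stood higher, with 3 of 7 members rising, none falling (1 without transitional replicate B) and a median log2 change of 2.90, which was 1.08 without vegetative replicate D. Adjusted over the list alone, 5 of them rose and 1 fell. By camera, limma's test of a list against all other genes, the adjusted p was 2.4e-12 for the MADS-box list and 0.00136 for the regulators. Both were 0.348 with an estimated correlation between members. Under a filter of at least 1 CPM in 2 libraries the medians were 3.22 for the MADS-box list and 2.16 for the regulators. The members that set the unfiltered medians stood between 0 and 1.96 normalised counts in the vegetative libraries. In the vegetative group, 8 of the 11 MADS-box members stood higher in replicate C than in D, by a median log2 difference of 0.69 over the list. Among these, 1 stood at 2.76 against 1.96 normalised counts and 1 at 1.38 against 0, where few reads decide. Within the transitional group 8 of 11 stood higher in A than in B.

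The other flowering lists were less uniform. In the florigen family (CETS genes, which include the mobile flowering signal and its antagonists), 1 of 3 tested members rose and none fell, with 2 rising when adjusted over the list alone, and the median log2 change was 2.95. That median was 4.83 without vegetative replicate C and 1.08 without D. The member that rose was entered in the list as an antagonist. The member entered as the flowering signal was not called over all genes. It stood at 12.4 and 0 in vegetative C and D and at 27.4 and 27.3 in transitional A and B. The remaining 6 of the 9 CETS identifiers had no read in any library. The list did not pass the camera test (adjusted p = 0.0541, and 0.562 with an estimated correlation). Without vegetative replicate C its camera adjusted p was 0.0032, and without transitional replicate B it was 0.0159. Of the B and C class genes, which specify petals, stamens and carpels, 4 of 8 identifiers had no read in any library, and 1 of the 3 tested rose, by 3.79 on the log2 scale. Without transitional replicate A none of the 3 rose, and without B 1 rose and 1 fell, while DESeq2, and limma under a filter of at least 1 CPM in 2 libraries, called 0 of them higher. Adjusted over that list alone 1 rose, and the list was not called, with a median log2 change of 0.02 (0.22 without transitional replicate A), a mean of 1.09 and a camera adjusted p of 0.484.

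Among SBP-box genes, which promote phase change, 1 of 12 rose and 1 fell, with a median log2 change of 0.11 and a camera adjusted p of 0.236. The SBP-box median was 0.04 without vegetative replicate C and 0.18 without D. Adjusted over the list alone, 2 rose and 1 fell. AP2-like genes, a class that includes repressors of flowering, stood lower as a list, with a median log2 change of -0.39. Singly, 1 of 8 members fell and none rose, and adjusted over the list alone 3 fell and 1 rose. The camera adjusted p of the AP2-like list was 0.0188, and 0.562 with an estimated correlation. Without vegetative replicate D it was 0.142, and without transitional replicate A it was 0.0623. Without transitional replicate B the AP2-like median was -0.61 and 2 members fell, and without either transitional replicate in turn 2 SBP-box members rose.

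Genes of meristem maintenance, including the WUSCHEL, CLAVATA and KNOX classes that keep or restrict the stem cell pool, stood lower as a list at the transition. Of 10 members 2 fell, by log2 changes of -0.73 and -0.97, and none rose. Adjusted over the list alone, 4 fell and 1 rose. Both members that fell over all genes were entered in the list as CLAVATA class, which restricts the pool. The member entered as WUSCHEL stood higher, by 0.47 on the log2 scale, and was not called over all genes. The list median was -0.24 with a camera adjusted p of 0.00443, and an adjusted p of 0.562 with an estimated correlation. Leaving out transitional replicate A, 4 members fell, and leaving out B, 3 did and the median was -0.13. Of the 4 genes of organ boundaries and axillary meristems, 1 rose, by 1.37 on the log2 scale, and none fell by limma. Adjusted over that list alone, without transitional replicate B, and by DESeq2 with all libraries, 1 rose and 1 fell. The boundary list had a median of -0.02 and a mean of 0.16, opposite in sign, and a camera adjusted p of 0.794 in the upward direction, and its median was 0.04 without vegetative replicate D.

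Of 8 tested genes of gibberellin metabolism and signalling, a hormone pathway of stem growth and flowering, 4 rose by log2 changes of 0.84 to 4.57 and none fell. Adjusted over the list alone, 4 rose and 2 fell. Over the list the median was 0.49, against 0.84 under a filter of at least 1 CPM in 2 libraries, and the camera adjusted p 0.00871, against 0.647 with an estimated correlation. Without transitional replicate A it was 0.3, and 3 members rose and 1 fell. All 8 members stood higher in transitional A than in B, by a median log2 difference of 0.46. Of 4 tested PIN auxin transporters, 1 rose and none fell, both over all genes and adjusted over the list alone. The PIN median was 0.73, against 0.21 under the filter of at least 1 CPM in 2 libraries, with a camera adjusted p of 0.0225, and 0.473 with an estimated correlation. Without vegetative replicate D it was 0.117, and without transitional replicate B 2 members rose.

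Circadian clock and photoperiod genes changed in both directions. Of 14 members 3 rose, by log2 changes of 1.41 to 1.81, and 3 fell, by log2 changes between -0.49 and -1.56; adjusted over the list alone, 4 rose and 4 fell. Over all 14 the median was 0.11, and 0.07 without vegetative replicate D. Camera gave no shift of the list (adjusted p = 0.735, upward), and fry, which tests the list without reference to other genes, gave an adjusted p of 0.301 in the downward direction and 0.0129 for change in either direction, a test that 9 of the 15 lists passed.

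**Figure D2:**
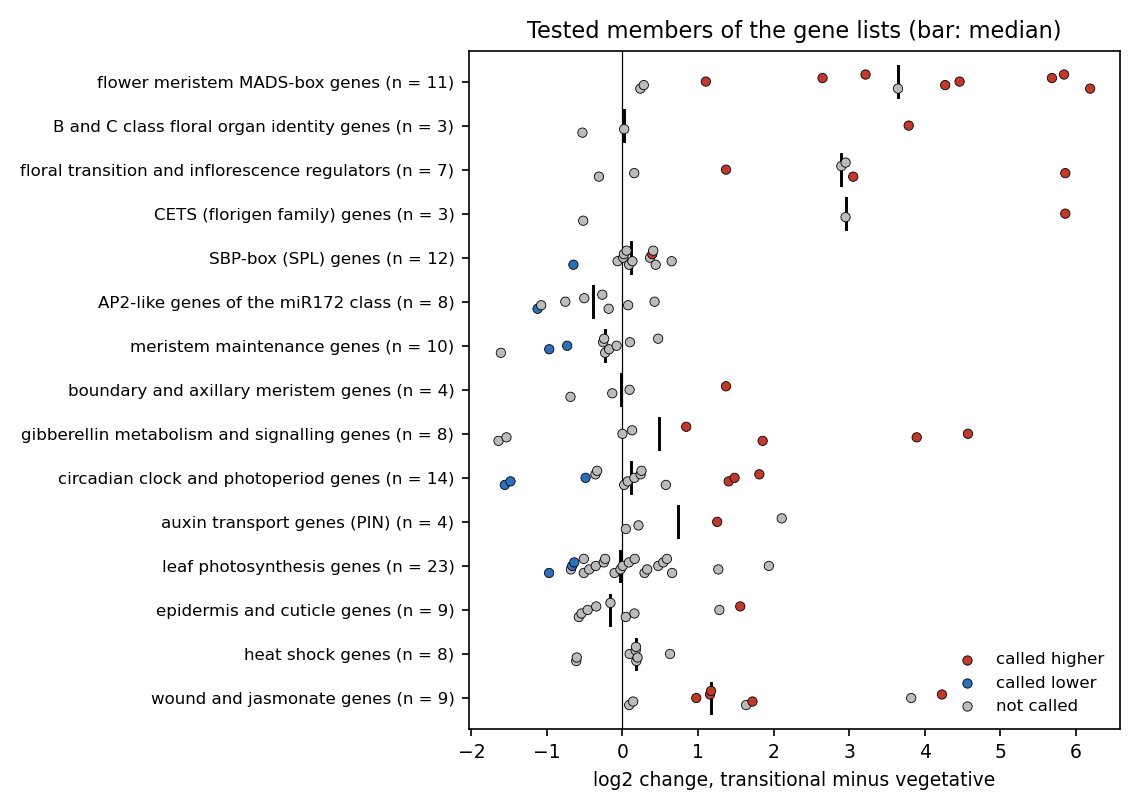
Each point is a tested member of a gene list, placed by its log2 change, transitional minus vegetative; red points were called higher, blue points lower and grey points neither, and black bars are list medians. The MADS-box median lies at 3.65, and called clock members lie on both sides of 0.

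Lists for other tissues and for handling were read alongside. Wound and jasmonate genes, induced by damage and by the hormone jasmonate and listed as markers of handling, stood higher in transitional meristems. A difference in handling between the stages would move with the same libraries and cannot be told apart from stage. Of 9 tested members 5 rose, by log2 changes of 0.98 to 4.23, and none fell; 7 rose when adjusted over the list alone. The median log2 change was 1.17, and the camera adjusted p was 4.05e-08, against 0.348 with an estimated correlation. Of the 9 members, 7 stood higher in transitional A than in B, by a median log2 difference of 0.37 over the list. Of the 13 identifiers 3 had no read in any library. No heat shock gene passed the test by limma, of 8 tested, over all genes or adjusted over the list alone, with 2 at an unadjusted p under 0.05, and the median was 0.18 with a camera adjusted p of 0.735. All 8 stood higher in transitional A than in B, by a median log2 difference of 0.65. For some of them, at 49.66 against 49.57 and at 28.38 against 28.33 normalised counts, the reads were equal and only the size factors differed. Of the heat shock genes 1 was called lower without transitional replicate A, where the median was -0.05, and 1 higher without B. DESeq2 called 1 higher with all libraries.

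Leaf photosynthesis genes, taken as markers of expanding leaf tissue, did not move as a block. Of 23 members 3 fell, by log2 changes of -0.64 to -0.97, and none rose; adjusted over the list alone, 6 fell, and DESeq2 also called 6 lower. The median log2 change was -0.03 and the mean 0.04, while camera called the list lower (adjusted p = 0.0398, and 0.765 with an estimated correlation). The 9 members with a mean of at least 1000 normalised counts had a median log2 change of -0.51 and the other 14 members one of 0.31, a division made after the values were seen. All 23 stood higher in transitional A than in B, by a median log2 difference of 0.55. Without transitional replicate A the median was -0.50, 7 members fell and none rose, and without B 2 rose and 3 fell. Without B the camera direction also turned upward, with a median of 0.21 and an adjusted p of 0.712; without vegetative replicate D the adjusted p was 0.236. Of 9 tested genes of the epidermis and cuticle 1 rose, by 1.56 on the log2 scale, and none fell by limma. Adjusted over the epidermis list alone, and by DESeq2, 1 rose and 2 fell. With limma under the filter of 1 CPM or a pseudocount of 5, 1 rose and 1 fell, and limma-voom called 0 higher. The epidermis median was -0.16 and the mean 0.11, with a camera adjusted p of 0.484 in the downward direction. That median was -0.08 without vegetative replicate C and -0.0017 without D. Without transitional replicate A 1 epidermis gene fell and none rose, and without B 1 rose and 2 fell.

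**Figure D3:**
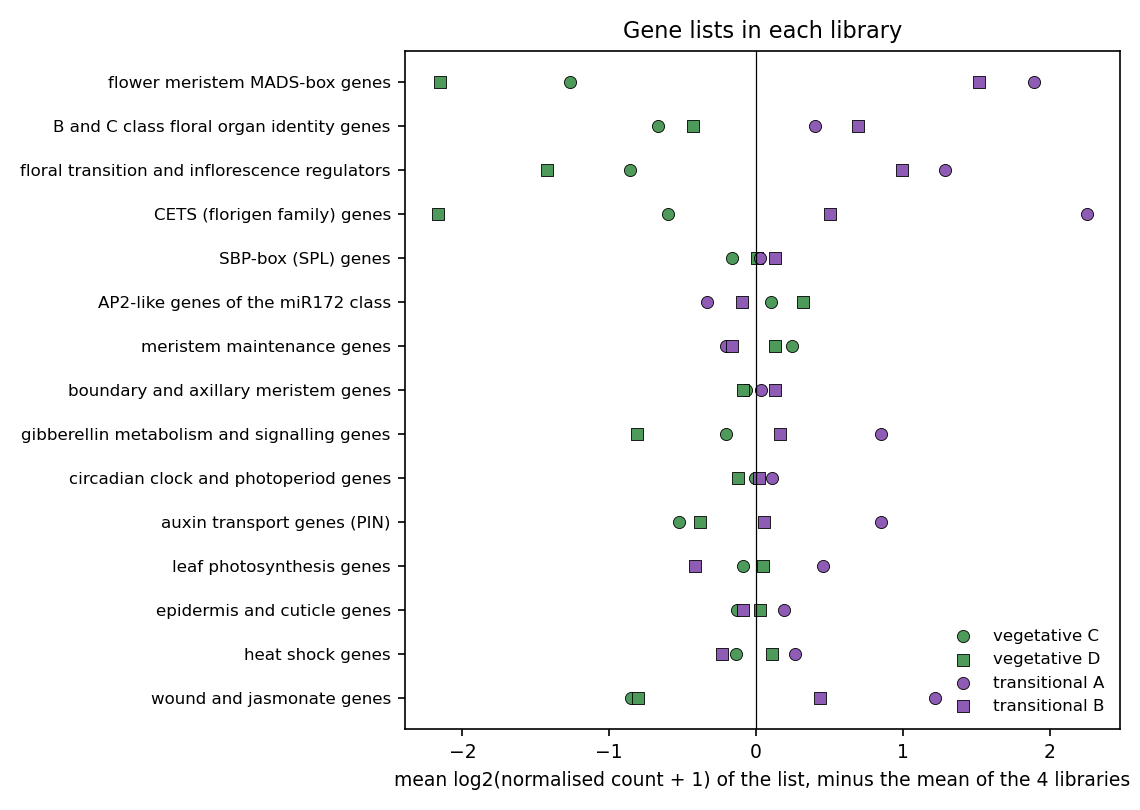
Each point is the mean log2(normalised count + 1) of a list in 1 library, minus the mean over the 4 libraries; circles and squares are replicates, green for vegetative and purple for transitional. The photosynthesis list lies at 0.46 in transitional A and -0.41 in B, with both vegetative libraries between them.

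By camera with a preset correlation of 0.01, 8 of the 15 lists were called. With an estimated correlation 0 were called, and by fry's directional test 0 were called, the smallest adjusted p being 0.0656. For change in either direction fry called 9 of the 15. Some identifiers belong to more than 1 list, so the lists are not independent of one another. The CETS gene that rose and the boundary gene that rose are the same genes as members counted among the risen floral transition regulators.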

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

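With all 4 libraries, the counts of genes called moved by more than 1.5 times under 2 settings. Without a filter limma called 6 genes higher and 1 lower, where the prior degrees of freedom fell from 5.18 to 2.58 as near-silent genes entered. Against a 1.5-fold change it called 115 and 23. DESeq2 called 576 and 311 and voom 431 and 212, sharing 666 and 638 of the 762 genes. No called gene changed direction in any setting. Leaving out 1 library gave 0 to 776 genes higher and 0 to 478 lower, and the lone sample of a group was then assumed to vary like the other group. The 0 came without vegetative replicate C or D (1577 and 1867 genes at an unadjusted p under 0.05), where the spread rested on transitional A and B alone. No other tool was run on 3 libraries. Camera called 8 lists, and 5 to 9 when 1 library was left out. With an estimated correlation it called 0, and fry's directional test called 0. The PIN and floral transition lists lost their camera calls though their estimated correlations, 0.0151 and -0.0925, lay near or below the preset 0.01. A higher correlation between members therefore does not account for the loss in those lists. The other called lists had estimates of 0.23 to 0.785. The estimated form also uses the residual degrees of freedom, 2 here, which alone raises the p-values. How much of the loss came from each was not tested. The photosynthesis list turned upward without transitional replicate B (adjusted p = 0.712), its median running from -0.50 to 0.21 when 1 library was left out, and the cause was not tested. All 4 genes given by identifier kept their direction in every setting tabulated for them, which leaves out the 1.5-fold test. Among these, Solyc08g006860.2 lost its call without vegetative C or D, and the other 3 also without the filter. Counting error limits genes near 0, and 2 libraries per group limit the rest.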

Other observations

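The explanation tests, the test of neighbouring genes and the division of clock genes by time of day were all chosen after the results were seen. Genes that rose lay beside one another in identifier order more often than shuffled calls did. There were 53 adjacent pairs of risen genes, against a mean of 14.3 and a highest value of 30 in 10000 permutations (permutation p = 0.0001, the smallest these permutations can give). For genes that fell there were 11 pairs against a mean of 2.76 (permutation p = 0.0002). Neighbours that are copies of one gene and share reads were not separated from others here. Of the genes that rose, 70.5% stood higher in transitional A than in B (exact 95% interval 66.4 to 74.4), against 52.6% of all tested genes and 48.9% of those that fell.

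MADS-box list members stood higher in vegetative replicate C than in D for 8 of 11 members. The lean was not particular to that list. In C, 7 of 8 gibberellin, 10 of 10 meristem maintenance and 12 of 14 clock members stood higher. Their median log2 differences were 0.50, 0.10 and 0.11. Other lists leaned towards D, with 4 of 23 photosynthesis, 2 of 8 heat shock and 1 of 9 wound members higher in C. Of the genes called higher, 46.9% stood higher in C than in D (exact 95% interval 42.5 to 51.3, with genes taken as independent). These genes thus showed no shift of C towards the transition. A call favours genes with a small spread between C and D, so genes on which C had advanced could be missed. Replicate C standing further along as a whole was therefore not excluded. Over 12 genes outside the list with at most 3 reads in D, the reads in C allowed a share of transitional RNA, of the kind in A and B, of up to 2.79%, since a gene's own reads in C can only raise that share. This limit pools the 12 genes, and taken singly they gave shares from 0 to 12.7%. The 7 members with a mean of at least 100 normalised counts exceeded D by a median of 0.59 on the log2 scale beyond what the pooled 2.79% gives. The SD between C and D for genes of such a mean was 0.19, and 4 of the 7 lay above the limit by more than 2 SD and 1 below. That SD goes by the overall mean, while 1 member stood at only 2.76 and 1.96 in C and D. The pooled share thus fell short of the excess for that part, but transitional RNA as the whole cause was not excluded. For the 4 members with a lower mean the median lay at -0.48, within an SD of 0.76, and transitional RNA in C cannot be told apart from other differences at these low counts, while a difference in stage that touched few genes was not tested.

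Clock list members moved both ways. A candidate explanation is collection at another time of day. Members known for afternoon or evening peaks (6) had a median log2 change of 0.99 and morning members (4) one of -0.42, a difference of 1.41 (two-sided exact permutation p = 0.0286). The permutation took genes as independent, though all were measured in the same 4 libraries, so its p-value does not measure the spread between samples. The labels used here give no time of collection, and the values had been seen before the members were divided. Of the 14 members 4 were left out, among them the one with the largest fall, of -1.56 on the log2 scale. A change of clock genes with the stage itself was not tested and would move with the same libraries, so the time-of-day reading is a hypothesis.

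All photosynthesis and heat shock list members tested stood higher in transitional A than in B, by medians of 0.55 and 0.65 on the log2 scale. Some heat shock members, at 49.66 against 49.57 and at 28.38 against 28.33 normalised counts, had equal reads in A and B. Only the size factors set those apart. The median difference of all tested genes was 0.0097, so these lists departed from the typical gene. The deposited values had already been divided by size factors, which bring that median near 0. The median of all genes therefore cannot by itself exclude a scaling error between the replicates. Such an error is 1 factor per library and moves all genes about alike. It cannot set these lists apart from the typical gene. The list medians of 0.55 and 0.65 against 0.0097 thus argue against it as the cause of that departure. More leaf tissue in A, or a difference in handling or temperature, stays open and was not tested. The labels give no batch. No biological explanation was tested, since both libraries belong to 1 stage.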
